A study of Mus musculus with 4 samples.

How the data were processed

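RNA-seq libraries were made from GFP-positive cells sorted from the dissected anterior and intermediate lobes of POMC-EGFP mice of strain C57B6, with 2 corticotrope and 2 melanotrope libraries, per the labels. RNA was depleted of ribosomal RNA and sequenced as 50 bp paired-end reads on an Illumina HiSeq, per the labels. The labels do not say whether replicates came from separate sorts or animals, so the spread between these libraries may be technical. The p-values rest on that spread, moderated by a prior drawn from all genes.

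FPKM values, 1 per RefSeq transcript and library, were made by the authors with HOMER's analyzeRepeats on mm10 with exon counting, per the file headers. The authors' log2 fold change, mean log2 value, p-value and FDR columns came from HOMER's getDiffExpression, which was run on the table of FPKM values, per the file headers. The submitters' processing notes name TopHat, HOMER and edgeR and the builds GRCm38 and mm10, and their versions are not given in the sources used here. Whether counting used strand is not given in the sources used here. The deposited fold column held 10 to the power of the log2 fold change in 100% of rows (within 0.01%), so this ratio was not used. Of 10791 transcripts under 0.5 FPKM in all 4 libraries, 99.3% had a deposited log2 fold change of exactly 0. FPKM columns were deposited with nearly equal sums, 729485 and 729483 in corticotropes and 729482 and 729482 in melanotropes, so a larger share for Pomc lowers all other values of a library.

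Read counts were inferred from low values. FPKM times transcript length fell on whole multiples of 1 step (within 0.1 step) for 99.7% to 100% of the low values used. The inverse of the step gave the reads per unit of FPKM times length, from which read counts were implied. Whether a read pair counted as 1 or 2 is not given in the sources used here. FPKM were deposited to 2 decimals, so low genes carry rounding error.

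The design written before the data were examined used a test on counts with TMM scaling. It named limma with a trend on log2(value + 1) of the 4 columns as the fallback for normalized values, without naming a scaling. Because the columns held FPKM, the fallback was used. TMM scaling was kept, and the filter and the transcript standing for each gene were chosen, after the values had been seen. The unscaled fit was among the alternatives fixed beforehand and is given beside the rescaled counts. The trimmed mean of M values was computed without weights, trimming 30% of M and 5% of A on each side, and gave factors of 1.21 and 1.16 for corticotropes and 0.874 and 0.819 for melanotropes, by which the columns were divided. Each gene was represented by its longest transcript. Genes with at least 1 FPKM after rescaling in at least 2 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05) on log2(FPKM + 1), with cell type as the sole term. Fold changes are melanotrope over corticotrope on that scale, which understates the change of low genes. The fit had 2.00 residual and 3.80 prior degrees of freedom, and the median standard error of a log2 fold change was 0.09.

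Gene lists, 32 in number, and the rule for named genes were fixed before the data were examined. The rule took 11 genes in any case, the 10 genes per direction with the largest fold change among those past the threshold with at least 10 FPKM in the higher cell type and separated libraries (leaving out unnamed models and small RNAs), and up to 2 members per direction of each described list with the smallest adjusted p. The rule was written in CPM and was applied in FPKM. Genes named outside it, mainly further list members, were chosen after their values were seen, and some list members are not reported here. Lists with at least 3 measured members were tested with camera (preset correlation 0.01), camera with an estimated correlation, and fry, with Benjamini-Hochberg adjustment over 31 lists. With an estimated correlation camera tests on the 2.00 residual degrees of freedom, so a list can miss the threshold there whatever its correlation. The list of mitochondrially encoded genes had 0 transcripts in the table and was not analysed here. A replicate block, leave-one-out fits, other scalings, filters, pseudocounts, transcript choices and prior variances were run as alternatives. Coordinates are those of the deposited table on mm10, counted from 1, for the longest transcript.

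The fit was tested on simulated data for the melanotrope over corticotrope comparison with 13046 genes, of which 200 were changed. Of 100 genes changed by 1 on the log2 scale 100% were recovered, likewise of 100 changed by 2, with 6 false calls. The changed genes were drawn from those above low expression, in equal numbers each way, with noise from the fit's own moderated variances. The simulation held no shift like that of Pomc, so it does not show recovery of low genes or under such a shift. A simulated list of changed genes, drawn independently, was called by camera, also with an estimated correlation (adjusted p = 0.0122). Camera called 0 of 5 unchanged lists. The adjustment ran over the simulated lists alone, which were far fewer than the gene lists tested here. The simulation therefore does not show that camera with an estimated correlation can call a list after adjustment over all gene lists. Tables were prepared in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.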

Results

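Transcriptomes were measured by RNA-seq in the pair of pituitary cell types that make pro-opiomelanocortin (POMC), the precursor of ACTH, α-MSH and β-endorphin. Corticotropes of the anterior lobe and melanotropes of the intermediate lobe were sorted by GFP from mice that carry EGFP under control of Pomc, after the lobes had been parted by dissection. Each cell type had 2 libraries, 4 in all. The deposited table gave FPKM values for 33072 RefSeq transcripts of 24063 genes on mouse build mm10. Depth was not listed, but the spacing of low FPKM values gave the reads behind 1 unit of FPKM times length. This was lowest in corticotrope replicate 1 and 2.00, 1.90 and 2.04 times as high in the other libraries. It is not a depth, because the columns were deposited with nearly equal sums. The implied read counts over the longest transcript of each gene were 97590687 and 187290691 in corticotropes, and 146148115 and 149792262 in melanotropes. The 5 Pomc transcripts took 27.8% and 27.2% of the summed FPKM in the corticotrope libraries and 49.7% and 50.9% in melanotropes. Each transcript was counted separately, so reads shared between them may enter several times, and this is not the share of Pomc in the RNA. All FPKM below are rescaled between libraries unless they are called deposited, and values are means ± SD with n = 2 per cell type, corticotropes first. Beside an adjusted p under an alternative setting stands its range over the 12 to 15 alternatives run for that gene or list. Where leaving out 1 library moved a list's higher or lower count by over 1.5 times, the counts without it are given (limma). The expression filter then needs a library of the other cell type at 1 FPKM, so that genes of 1 cell type alone drop out.

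The comparison asked which genes differ between melanotropes and corticotropes. Melanotropes had more of the transcripts for the transcription factor Pax7, the convertase Pcsk2, the dopamine receptor Drd2 and the acyltransferase-family gene Oacyl. Corticotropes had more Crhr1 and Avpr1b, the receptors for CRH and vasopressin, more glucocorticoid receptor (Nr3c1) and more Neurod1. Transcripts of other anterior-lobe hormones, Gh and Prl foremost, were also higher in the corticotrope libraries. Of 13046 genes tested, 4859 passed an adjusted p of 0.05, 2469 of them higher and 2390 lower in melanotropes. At 2-fold or more there were 1158, with 538 higher and 620 lower, and at 16-fold or more there were 16, all lower in melanotropes. With a pseudocount of 5 in place of 1 there were 404 at 2-fold and 4 at 16-fold, and with one of 0.1 there were 11 higher and 58 lower at 16-fold. At 2-fold the lower count was 392 without corticotrope replicate 1 (502 higher) and 367 without corticotrope replicate 2 (504 higher), where 9 and 7 were lower at 16-fold, and on the deposited scale 1197 were lower and 282 higher. Libraries of one cell type correlated across genes at r = 0.992 (corticotropes) and 0.993 (melanotropes), and libraries of different cell types at 0.915 to 0.921, where genes are not independent replicates. Without melanotrope replicate 1 the count was 3187 (1579 higher and 1608 lower), and without melanotrope replicate 2 it was 3076 (1403 higher and 1673 lower). Without rescaling, on the deposited scale, 939 genes were called higher and 8787 lower, around a median log2 fold change of -0.42. Changes below are therefore relative to the median gene, which lay at 0.00 after rescaling.

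**Figure D1:**
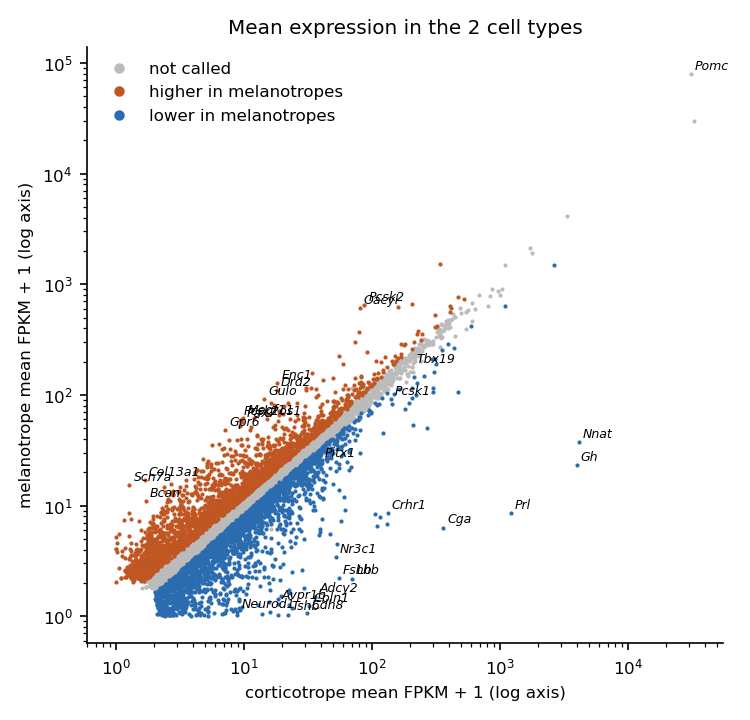
Mean FPKM + 1 in corticotropes (x, log axis) and melanotropes (y, log axis) for the 13046 genes tested, each a point, means of 2 libraries. Orange and blue points passed an adjusted p of 0.05; the points farthest from the diagonal, such as Gh and Nnat, lie on the corticotrope side.

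Pomc itself (chromosome 12, 3954945 to 3960643) was listed at 30954 ± 459.6 against 79119.6 ± 5081 FPKM, a log2 difference of 1.35 with a standard error of 0.77 and an adjusted p of 0.222 (limma). Both melanotrope libraries lay above both corticotrope libraries. The standard error was moderated toward a trend over genes of similar level, and the SDs of the replicates are small beside the difference. The adjusted p is therefore not a measure of replicate spread alone. The difference passed the threshold under 4 of 14 alternatives and missed it under the other 10 (adjusted p, range 7.63e-09 to 0.974). Of those 4, 3 were added after the data were seen. They were a single prior variance for all genes, a pseudocount of 5 and equal sums of the other transcripts. The single prior variance was added because Pomc had missed the threshold. The fourth, replicate number as a block, was fixed beforehand. Same-numbered libraries share only a number in the labels, but their deviations correlated at 0.525 across genes, so a pairing is not excluded. Tbx19 (chromosome 1, 165137853 to 165160773), the T-box factor of the POMC lineage, was at 205 ± 6.95 against 176 ± 4.26 FPKM (log2 difference -0.22, adjusted p = 0.109), and it was called lower under 2 of 15 alternatives, 1 of them the deposited scale (adjusted p = 0.00122; range 0.00122 to 0.378). Of 12 measured genes of the POMC lineage list, 3 rose and 5 fell in melanotropes, and adjusted over the list alone 3 higher and 6 lower. The lineage counts were 2 higher and 3 lower without corticotrope replicate 2 or melanotrope replicate 2. Neurod1 (chromosome 2, 79452641 to 79456636), a bHLH factor of corticotrope differentiation, was lower in melanotropes at 7.90 ± 0.540 against 0.0954 ± 0.0379 FPKM, a log2 fold change of -3.02. Pitx1 (chromosome 13, 55825054 to 55831425) was lower in melanotropes at 39.1 ± 0.559 against 24.4 ± 1.93 FPKM. The nuclear receptor Nr4a1 was higher at 169 ± 22.2 against 287 ± 11 FPKM and was not called on the deposited scale (adjusted p = 0.0986; range 2.17e-06 to 0.0986). As a whole the list did not pass the test against other genes (camera adjusted p = 0.485), and on the deposited scale it had 1 higher and 8 lower.

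**Figure D2:**
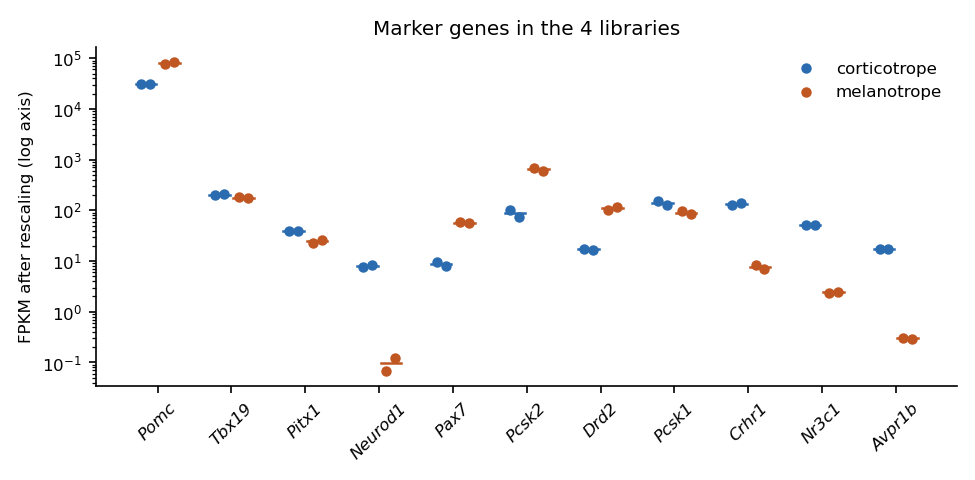
FPKM after rescaling (log axis) of the 11 genes fixed beforehand. Each point is a library, bars are means of 2 libraries, corticotropes blue and melanotropes orange; Pax7, Pcsk2 and Drd2 lie higher in both melanotrope libraries, and Crhr1, Nr3c1, Avpr1b and Neurod1 in both corticotrope libraries.

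All 7 melanotrope markers rose in melanotropes, and all 7 also when adjusted over the list alone (camera adjusted p = 1.19e-06; adjusted p = 0.784 with an estimated correlation). Pax7 (chromosome 4, 139738081 to 139832968) was at 8.74 ± 1.14 against 56.4 ± 1.76 FPKM, with a log2 fold change of 2.56 (SE 0.10, adjusted p = 5.91e-05). Pcsk2 (chromosome 2, 143546133 to 143816282), the convertase that cuts ACTH to α-MSH, was at 86.7 ± 18.9 against 643 ± 61.5 FPKM and Drd2 (chromosome 9, 49340662 to 49407214) at 17.1 ± 0.762 against 109 ± 7.41 FPKM, with log2 fold changes of 2.89 and 2.60. Oacyl was at 79.8 ± 18.2 against 605 ± 73.6 FPKM, and Gulo, an enzyme of vitamin C synthesis, was at 13.4 ± 0.106 against 90.3 ± 4.89 FPKM. Posterior lobe and glia markers were higher (6 of 8) and other-lineage markers lower (13 of 13) in the same melanotrope libraries. In the corticotrope libraries the 7 markers stood at 13.2% to 21.3% of their melanotrope level.

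Of 6 measured corticotrope markers 5 fell in melanotropes and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00327; adjusted p = 0.784 with an estimated correlation). The camera adjusted p on the deposited scale was 0.192 (range 5.05e-04 to 0.192), although 5 members were called lower there too. Crhr1 (chromosome 11, 104132882 to 104175518) was at 132 ± 7.55 against 7.56 ± 0.900 FPKM (log2 fold change -3.96, SE 0.10, adjusted p = 2.57e-05). Avpr1b (chromosome 1, 131599114 to 131612000) was at 17.5 ± 0.190 against 0.301 ± 0.0110 FPKM and Nr3c1 (chromosome 18, 39410545 to 39487245) at 51.5 ± 1.27 against 2.42 ± 0.0375 FPKM, with log2 fold changes of -3.83 and -3.94. Pcsk1 (chromosome 13, 75089987 to 75132498), the convertase that releases ACTH from POMC, was lower at 139.5 ± 16.2 against 90.1 ± 8.48 FPKM (log2 fold change -0.62). The member that rose was Gpr165, an orphan receptor, at 4.51 ± 0.154 against 19.7 ± 0.620 FPKM. Markers of other anterior-lobe lineages were lower in the same libraries, 13 of 13. Cyp11a1, the seventh gene of the list, did not pass the expression filter.

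The genes with the largest differences beyond these lists were named by the same fixed rule. Higher in melanotropes were Scn7a, Col13a1, Enc1, Gpr6, Bcan, Pcsk2os1 and Megf11. Scn7a was at 0.280 ± 0.0688 against 14.4 ± 0.772 FPKM (log2 fold change 3.59), Col13a1, a transmembrane collagen, at 0.691 ± 0.345 against 15.9 ± 1.67 FPKM, and Enc1, an actin-binding protein, at 17.3 ± 1.06 against 126 ± 5.20 FPKM. Pcsk2os1 overlaps Pcsk2 on the other strand, and no strand setting is stated, so its value of 8.33 ± 1.82 against 58.9 ± 5.15 FPKM is uncertain. Lower in melanotropes, besides the hormones described below, were the imprinted gene Nnat at 4118 ± 683 against 36.6 ± 6.75 FPKM (log2 fold change -6.78), Cdh8 at 30.2 ± 5.92 against 0.0706 ± 0.0134, the cerebellin Cbln1 at 31.7 ± 4.30 against 0.237 ± 0.0110 and the adenylyl cyclase Adcy2 at 35.2 ± 2.67 against 0.507 ± 0.0265 FPKM.

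Receptors for hypothalamic and neural inputs went both ways. Of 13 expressed receptors 5 rose and 8 fell, adjusted over the list alone also 5 higher and 8 lower, and the list as a whole did not pass the test (camera adjusted p = 0.469). These counts depended on the corticotrope libraries, with 5 higher and 3 lower without corticotrope replicate 1 or 2, of 9 measured in each case. The list's median log2 fold change of -0.53 turned to 0.92 and 0.90 without them, and camera's direction turned from lower to higher (adjusted p = 0.596 and 0.480; range 0.192 to 0.956). Avpr1b, Sstr5 and Chrm2, lower with all libraries, did not pass the expression filter in either of those fits. The turn thus came with a loss of members. Sstr3 (log2 fold change -1.28 and -0.98) and Chrm4 (-1.21 and -1.16), still tested, stayed lower without corticotrope replicate 1 and 2. Sstr1, a somatostatin receptor, was at 10.4 ± 0.237 against 50.0 ± 1.75 FPKM, higher in melanotropes along with Drd2, Adrb1 and Oxtr, while Sstr3, Sstr5, Chrm2 and Chrm4 were lower along with Crhr1 and Avpr1b. Among 27 hormone and cytokine receptors 6 rose and 14 fell (adjusted over the list alone 6 higher and 15 lower). Egfr was lower at 13.4 ± 0.595 against 1.78 ± 0.233 FPKM, as was Nr3c1, and Fgfr2 at 1.38 ± 0.0755 against 6.58 ± 0.395 and Igf1r at 6.91 ± 1.15 against 14.5 ± 0.327 FPKM were higher. The shift of the receptor list (camera adjusted p = 0.0345) had an adjusted p = 0.829 with an estimated correlation. It was lost without corticotrope replicate 1 (adjusted p = 0.0814), corticotrope replicate 2 (0.0564) or melanotrope replicate 1 (0.0810), with a mean-based filter (0.0953) and on the deposited scale (0.722; range 0.00535 to 0.722), where it had 3 higher and 19 lower. Markers of other anterior-lobe lineages were also lower in these melanotrope libraries, 13 of 13.

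Genes known to respond to glucocorticoids were mostly lower in melanotropes. Of 17 measured members 13 fell and 4 rose, with the same counts adjusted over the list alone and a median log2 fold change of -1.24 (camera adjusted p = 0.00106; adjusted p = 0.8 with an estimated correlation). Fkbp5, a chaperone of the glucocorticoid receptor, was at 60.9 ± 8.26 against 8.13 ± 0.771 FPKM and the zinc finger factor Zbtb16 at 6.86 ± 1.49 against 0.668 ± 0.0395 FPKM. The members that rose were Per1, Errfi1, Dusp1 and Gadd45b, which also respond to growth factors or stress, with Dusp1 at 107 ± 4.67 against 203 ± 5.17 and Errfi1 at 25.3 ± 0.476 against 38.3 ± 1.13 FPKM. On the deposited scale the list's camera adjusted p was 0.192 (range 1.45e-04 to 0.192) and Errfi1 was not called (adjusted p = 0.189; range 1.85e-05 to 0.189). Per1 was not called there (adjusted p = 0.971), nor with no expression filter (0.0683), without corticotrope replicate 2 (0.113) or without melanotrope replicate 2 (0.0926; range 0.00195 to 0.971). Markers of other anterior-lobe lineages were lower in melanotropes in the same libraries, 13 of 13.

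Genes of the secretory pathway were shifted in part. Of 23 genes of the unfolded protein response, 12 rose in melanotropes and 0 fell, also 12 and 0 adjusted over the list alone (0 lower too at an unadjusted p under 0.05, limma), with a median log2 fold change of 0.37 (camera adjusted p = 0.00497; adjusted p = 0.914 with an estimated correlation). Markers of other anterior-lobe lineages were lower (13 of 13) and those of the posterior lobe and glia higher (6 of 8) in the same melanotrope libraries. Without rescaling 0 rose and 4 fell, although the list still stood above other genes (camera adjusted p = 0.0126). Xbp1 was at 74.7 ± 0.263 against 111 ± 5.59 FPKM and Sdf2l1 at 28.5 ± 0.390 against 47.3 ± 5.01 FPKM, and neither was called on the deposited scale (Xbp1 adjusted p = 0.382, range 1.40e-05 to 0.382; Sdf2l1 adjusted p = 0.108, range 8.54e-06 to 0.108). Without melanotrope replicate 1 the list had 5 higher and 2 lower members and a camera adjusted p of 0.0810 (range 7.43e-05 to 0.0810), and without corticotrope replicate 1 or 2 it had 6 or 7 higher members. Of 14 prohormone processing genes 4 rose and 5 fell, adjusted over the list alone 6 higher and 5 lower (camera adjusted p = 0.902). The prohormone list had 1 higher and 7 lower on the deposited scale, and 2 higher and 3 lower without corticotrope replicate 1 or 2 and 2 higher and 5 lower without melanotrope replicate 2. Besides Pcsk2, the amidating enzyme Pam was higher at 227 ± 13.0 against 378 ± 16.5 FPKM (deposited scale adjusted p = 0.0755; range 8.53e-07 to 0.0755), and Pcsk6 at 4.73 ± 0.488 against 0.666 ± 0.0441 and Ece1 at 47.2 ± 3.86 against 31.9 ± 1.09 FPKM were lower. Of 27 genes of granins and dense core granules 9 rose and 3 fell, adjusted over the list alone 10 higher and 3 lower (camera adjusted p = 0.0668; range 0.0294 to 0.149). Without rescaling 5 of them were higher and 12 lower, and the granin counts were 7 higher and 1 lower without corticotrope replicate 1 or melanotrope replicate 1. The synaptotagmin Syt7 was at 5.34 ± 0.213 against 14.4 ± 0.837 FPKM and the Rab effector Rph3a at 0.744 ± 0.0480 against 4.15 ± 0.408, both higher, and Rab3b was lower at 29.1 ± 1.18 against 17.7 ± 3.93 FPKM.

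**Figure D3:**
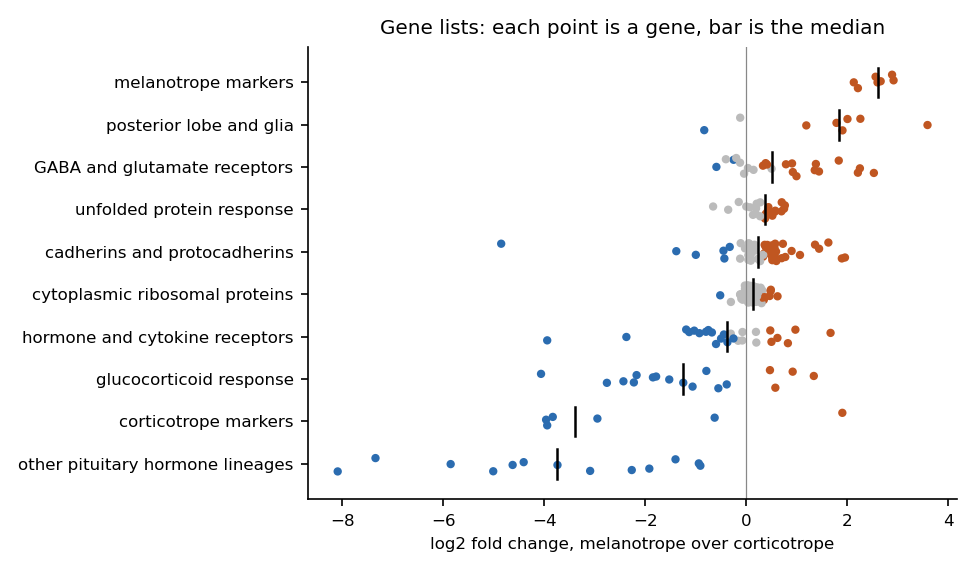
Log2 fold change (melanotrope over corticotrope) of each measured gene in the 10 lists past an adjusted p of 0.05 by camera with a preset correlation of 0.01; grey points did not pass the test for single genes and bars are medians. Medians run from -3.74 for other pituitary hormone lineages to 2.60 for melanotrope markers; on the deposited scale members of the unfolded protein response, cadherin and ribosomal lists were mostly called lower or not called.

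Markers of other cell types differed between the sorted populations. All 13 measured genes of other pituitary hormone lineages fell in melanotropes, also 13 adjusted over the list alone (camera adjusted p = 4.04e-10; adjusted p = 0.784 with an estimated correlation). Gh was at 3990.5 ± 186 against 22.2 ± 25.5 FPKM, with deposited values of 3.67 and 32.9 in the melanotrope replicates. Prl was at 1219 ± 115 against 7.54 ± 5.76, the glycoprotein hormone subunit Cga at 359 ± 63.6 against 5.33 ± 1.96, Lhb at 69.4 ± 13.0 against 1.19 ± 0.473, Fshb at 54.2 ± 9.68 against 1.22 ± 0.0902 and Tshb at 21.1 ± 3.92 against 0.0351 ± 0.0151 FPKM. Lineage genes that are not hormones were lower too, among them Dlk1 at 21.7 ± 0.212 against 0.714 ± 0.234, Pou1f1 at 7.83 ± 1.48 against 0.0294 ± 0.00698 and Foxl2 at 1.2 ± 0.284 against 0.172 ± 0.0164 FPKM. When either corticotrope library was left out, 5 members passed the expression filter, which then needed a melanotrope library at 1 FPKM, and all 5 fell.

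Of 8 measured markers of the posterior lobe and glia, 6 rose and 1 fell in melanotropes, also 6 and 1 adjusted over the list alone (camera adjusted p = 0.00204; adjusted p = 0.784 with an estimated correlation). Besides Scn7a, oxytocin (Oxt) was at 0.00865 ± 0.0122 against 3.06 ± 0.134 FPKM, and the intermediate filament Vim was lower at 19.8 ± 0.384 against 10.8 ± 1.5 FPKM. The camera adjusted p was 0.260 without melanotrope replicate 1 and 0.133 without melanotrope replicate 2, each with 3 higher members of 5 measured (range 3.42e-09 to 0.260). Blood and immune markers were mixed, with 5 of 14 higher and 4 lower, adjusted over the list alone 6 higher and 5 lower. The blood and immune counts were 5 higher and 1 lower without corticotrope replicate 2 and 3 higher and 4 lower without melanotrope replicate 1 or 2. The microglial and macrophage genes C1qa at 2.01 ± 0.555 against 6.30 ± 1.05 and Csf1r at 0.480 ± 0.117 against 2.10 ± 0.457 FPKM were higher, and Hba-a1 at 5.01 ± 0.442 against 0.604 ± 0.304 FPKM, which shares its sequence almost entirely with Hba-a2, was lower. Of 10 endothelial and mural markers 3 rose and 5 fell (adjusted over the list alone 3 higher and 6 lower). The endothelial and mural counts were 3 higher and 3 lower without corticotrope replicate 1, 3 higher and 1 lower without corticotrope replicate 2, 1 higher and 4 lower without melanotrope replicate 1 and 1 higher and 3 lower without melanotrope replicate 2. Plvap was lower at 7.93 ± 2.62 against 1.65 ± 0.617 and Dcn higher at 2.69 ± 0.331 against 8.47 ± 2.07 FPKM. Of 11 stem and folliculostellate markers 5 rose and 5 fell (adjusted over the list alone 5 higher and 5 lower). The keratins Krt8 at 21.2 ± 1.46 against 83.4 ± 0.331 and Krt18 at 29.4 ± 1.42 against 114 ± 5.45 FPKM were higher, and Aldh1a2 was lower at 14.4 ± 2.90 against 1.27 ± 0.276 FPKM. As a whole these lists did not pass the test, with camera adjusted p = 0.999, 0.519 and 0.983 in that order. On the deposited scale the first (0.0422; range 0.0422 to 0.999) and the last (0.0422; range 0.0422 to 0.983) passed it, both as higher than other genes. There the blood and immune list had 5 higher and 6 lower and the endothelial and mural list 3 higher and 8 lower.

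The level of a gene in the cell type where it was lower differed between the directions. Among genes of at least 10 FPKM in the higher cell type, 41 of 2802 higher in corticotropes stood at under 10% of that level in melanotropes, and 10 stood at under 1%. In the other direction 3 of 3523 genes stood at under 10%, namely Scn7a, Col13a1 and Bcan, and 0 at under 1%. Without corticotrope replicate 2 there were 5 such genes, also Gpc3 and Igfbp4, and without melanotrope replicate 1 there were 3, with Igfbp4 in place of Bcan. Both further genes were named after their values were seen. Between 10% and 20% there were 48 genes higher in melanotropes and 38 higher in corticotropes.

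**Figure D4:**
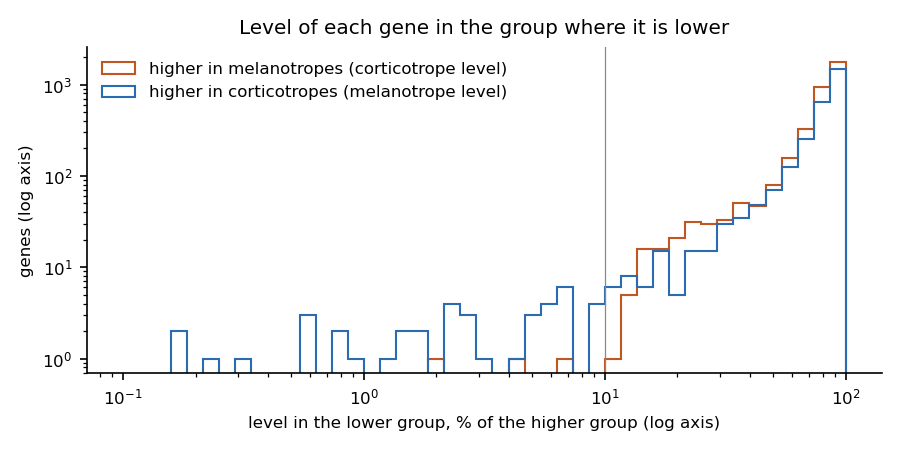
Number of genes (y, log axis) by the level in the cell type where a gene is lower, as % of its level in the other (x, log axis), for genes of at least 10 FPKM in the higher cell type. Genes higher in melanotropes (orange) end near 10%, the grey line, with 3 below it, and genes higher in corticotropes (blue) reach below 1%.

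Ion channel and receptor genes changed in both directions. Of 23 GABA and glutamate receptor genes 14 rose and 2 fell in melanotropes, adjusted over the list alone 15 higher and 3 lower (camera adjusted p = 9.14e-04; adjusted p = 0.8 with an estimated correlation). The kainate receptor subunit Grik3 was at 1.72 ± 0.370 against 14.6 ± 1.18 FPKM and the GABA receptor subunit Gabra2 at 4.22 ± 0.0395 against 23.2 ± 1.17 FPKM. The lower members were Grid1 at 1.18 ± 0.116 against 0.451 ± 0.0878 and Gabbr1 at 8.48 ± 0.0562 against 6.98 ± 0.116 FPKM, which were not called without melanotrope replicate 1 (adjusted p = 0.0558 and 0.218), and Gabbr1 also not without corticotrope replicate 1 (0.0876), corticotrope replicate 2 (0.107) or melanotrope replicate 2 (0.167). Gabbr1 also missed the threshold with no expression filter (0.0623), a single prior variance (0.0504) and equal sums of the transcripts other than Pomc (0.119), so that it passed under 8 of 15 alternatives, 5 fixed beforehand and 3 added. For Grid1 the adjusted p had a range 4.17e-04 to 0.0558, and for Gabbr1 a range 0.00142 to 0.218. The receptor counts were 13 higher and 0 lower (2 lower at an unadjusted p under 0.05) without corticotrope replicate 1, 10 higher and 0 lower (2 lower at an unadjusted p under 0.05) without melanotrope replicate 1 and 8 higher and 1 lower without melanotrope replicate 2. With no expression filter the list's camera adjusted p was 0.0926 (range 4.10e-09 to 0.0926). Markers of the posterior lobe and glia were higher (6 of 8) and those of other anterior-lobe lineages lower (13 of 13) in the same melanotrope libraries. Of 45 genes on the potassium channel list 19 rose and 15 fell (adjusted over the list alone 19 higher and 16 lower, camera adjusted p = 0.999). The list was drawn by symbol and also holds the noncoding Kcnmb4os1 and Kcnq1ot1. Kcnmb4os1, called higher, overlaps Kcnmb4 on the other strand, and no strand setting is stated, so its value is uncertain. The potassium channel counts were 15 higher and 7 lower without corticotrope replicate 1 and 13 higher and 8 lower without corticotrope replicate 2, each of 36 measured, and the median log2 fold change of 0.01 became 0.38 and 0.35. The list passed the test as higher than other genes without corticotrope replicate 1 (adjusted p = 0.0215) and on the deposited scale (0.0354; range 0.0215 to 0.999). Channels low in melanotropes, such as Kcng3 at 3.42 ± 0.148 against 0.135 ± 0.0355 FPKM, did not pass the expression filter when a corticotrope library was left out. The higher medians and the call without corticotrope replicate 1 thus came with a loss of such members. Kcnmb4, a subunit of BK channels, was higher at 18.0 ± 1.89 against 69.9 ± 0.465 FPKM, and the K2P channel Kcnk2 was lower at 27.6 ± 3.32 against 1.61 ± 0.476 FPKM. Of 15 calcium channel genes 5 rose and 3 fell (adjusted over the list alone 5 higher and 3 lower; camera adjusted p = 0.460, on the deposited scale 0.0422, range 0.0422 to 0.962). The calcium channel counts were 5 higher and 1 lower without corticotrope replicate 1 or melanotrope replicate 1 and 4 higher and 1 lower without melanotrope replicate 2. Cacna2d2 was higher at 2.11 ± 0.139 against 8.53 ± 1.16 FPKM and Cacna2d3 lower at 8.06 ± 0.330 against 2.48 ± 0.525 FPKM. Of 8 sodium channel genes Scn7a rose and 2 fell, among them Scn3b at 6.88 ± 0.832 against 3.35 ± 0.0977 FPKM (adjusted over the list alone 1 higher and 2 lower). The sodium channel counts were 0 higher and 2 lower (0 higher at an unadjusted p under 0.05) without melanotrope replicate 1 and 0 higher and 2 lower (1 higher at an unadjusted p under 0.05) without melanotrope replicate 2. Scn7a, under 1 FPKM in both corticotrope libraries, did not pass the expression filter in these fits and was not tested there. The sodium channel list had a median log2 fold change of -0.17 and a mean of 0.22, so that they differed in sign (camera adjusted p = 0.729). Without rescaling the GABA and glutamate receptor list had 11 higher and 7 lower. The potassium channel list had 10 higher and 22 lower there. The calcium channel list had 3 higher and 6 lower, and the sodium channel list 1 higher and 5 lower.

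Of 75 cadherin and protocadherin genes 35 rose and 6 fell in melanotropes, adjusted over the list alone 36 higher and 6 lower (camera adjusted p = 6.20e-05; adjusted p = 0.829 with an estimated correlation). On the deposited scale 12 rose and 37 fell, and without melanotrope replicate 2 the camera adjusted p was 0.0510 (range 7.95e-07 to 0.0510). The cadherin counts were 26 higher and 1 lower without corticotrope replicate 1, 26 higher and 0 lower (2 lower at an unadjusted p under 0.05) without corticotrope replicate 2, 25 higher and 3 lower without melanotrope replicate 1 and 21 higher and 4 lower without melanotrope replicate 2. Posterior lobe and glia markers were also higher (6 of 8) and other-lineage markers lower (13 of 13) in these libraries. Genes of the alpha and of the gamma protocadherin cluster share exons within their cluster, so their separate values are uncertain. Their estimated correlations were 0.930 (alpha) and 0.998 (gamma), far above the preset 0.01. The list's counts and its camera p therefore treat nearly shared values as separate genes. All 14 measured alpha genes rose, with log2 fold changes between 0.39 and 0.60, and 3 gene models that run from the alpha into the gamma cluster were not called. Of 22 gamma genes 0 were called (limma, 0 also at an unadjusted p under 0.05). Of 18 beta genes 9 rose and 2 fell, against 4 higher and 1 lower without corticotrope replicate 1, 3 higher and 0 lower (2 lower at an unadjusted p under 0.05) without corticotrope replicate 2, 4 higher and 0 lower (1 lower at an unadjusted p under 0.05) without melanotrope replicate 1 and 2 higher and 1 lower without melanotrope replicate 2. Among the 18 genes outside the clusters, 12 rose and 4 fell, against 8 higher and 0 lower (0 lower at an unadjusted p under 0.05) without corticotrope replicate 1, 10 higher and 0 lower (0 lower at an unadjusted p under 0.05) without corticotrope replicate 2 and 6 higher and 3 lower without melanotrope replicate 2. Cdh7 and Cdh8 did not pass the expression filter when either corticotrope library was left out, so they were not tested there. Cdh13 was higher at 1.25 ± 0.163 against 7.73 ± 0.0595 and Pcdh17 at 5.58 ± 0.0172 against 15.9 ± 0.142 FPKM. Cdh8 (chromosome 8, 99028769 to 99416471) and Cdh7 were lower, Cdh7 at 1.75 ± 0.416 against 0.0477 ± 0.0189 FPKM. Of 49 semaphorin, ephrin and axon guidance genes 15 rose and 16 fell (adjusted over the list alone 17 higher and 16 lower; camera adjusted p = 0.988, on the deposited scale 0.0360 as higher than other genes, range 0.0360 to 0.999), where 12 higher and 30 lower were called. The axon guidance counts were 13 higher and 10 lower without corticotrope replicate 1 and 15 higher and 9 lower without corticotrope replicate 2. Slit1 was higher at 7.90 ± 0.00399 against 38.2 ± 1.29 and Sema3e at 3.79 ± 0.112 against 25.1 ± 1.82 FPKM, and Sema4g was lower at 8.10 ± 0.183 against 2.10 ± 0.0610 and Epha5 at 7.90 ± 1.34 against 1.44 ± 0.0164 FPKM.

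Transcription factor families were split between the cell types, and no family passed the camera test as a whole. Of 36 genes on the homeobox list 12 rose and 6 fell (adjusted over the list alone 12 higher and 6 lower, camera adjusted p = 0.329). The list also holds the opposite-strand transcripts Msx1os, Six3os1 and Zfhx2os, of which Six3os1 was called, and with no strand setting stated their values are uncertain. The homeobox counts were 6 higher and 5 lower without corticotrope replicate 1 and 5 higher and 5 lower without melanotrope replicate 2. Pax7 was higher, and Pou1f1 and Satb1, the latter at 2.77 ± 0.121 against 1.16 ± 0.0711 FPKM, were lower. Of 27 genes on the bHLH list 6 rose and 12 fell (adjusted over the list alone 7 higher and 13 lower, camera adjusted p = 0.306). The list was drawn by symbol and also holds genes that are not bHLH factors, such as Hif1an and Tcf19. The bHLH counts were 5 higher and 6 lower without corticotrope replicate 1 and 6 higher and 6 lower without corticotrope replicate 2, each of 22 measured. Bhlha15 was higher at 4.97 ± 0.558 against 14.5 ± 0.786 FPKM. Neurod1 and Twist2, at 4.92 ± 0.0439 against 0.0713 ± 0.0200 FPKM, were lower. Of 29 genes on the SOX, forkhead and T-box list 7 rose and 5 fell (adjusted over the list alone 7 higher and 5 lower, camera adjusted p = 0.999). Among the 5 was Foxl2os, a noncoding RNA. Counts of the SOX, forkhead and T-box list were 7 higher and 3 lower without corticotrope replicate 1, 5 higher and 2 lower without corticotrope replicate 2 and 3 higher and 3 lower without melanotrope replicate 1 or 2. Sox11 at 1.32 ± 0.0484 against 4.79 ± 0.357 and Tbx3 at 0.406 ± 0.0109 against 2.04 ± 0.156 FPKM were higher. Of 34 nuclear receptors 12 rose and 11 fell (adjusted over the list alone 12 higher and 12 lower; camera adjusted p = 0.821). The nuclear receptor counts were 8 higher and 7 lower without corticotrope replicate 2, 7 higher and 11 lower without melanotrope replicate 1 and 6 higher and 12 lower without melanotrope replicate 2. Nr4a2 at 29.0 ± 7.49 against 79.2 ± 2.57 and Rarg at 3.13 ± 0.0705 against 6.67 ± 0.177 FPKM were higher. Nr3c1 and Nr5a1 were lower. Without rescaling the homeobox list had 5 higher and 15 lower and the bHLH list 4 higher and 17 lower. The SOX, forkhead and T-box list had 6 higher and 17 lower there, and the nuclear receptor list 4 higher and 19 lower.

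Lists of stress, sterol, interferon and cell cycle genes were also examined. Of 22 immediate early and dissociation genes 7 rose and 6 fell (adjusted over the list alone 7 higher and 7 lower; camera adjusted p = 0.983). The immediate early counts were 6 higher and 3 lower without corticotrope replicate 2 and 7 higher and 3 lower without melanotrope replicate 1. Egr3 was higher at 8.30 ± 0.948 against 18.8 ± 0.985 and Egr2 lower at 38.0 ± 7.09 against 11.3 ± 1.74 FPKM. Of 20 sterol synthesis genes 6 rose and 3 fell (adjusted over the list alone 6 higher and 3 lower; camera adjusted p = 0.983). The sterol synthesis counts were 6 higher and 1 lower without melanotrope replicate 1 and 3 higher and 3 lower without melanotrope replicate 2. Hmgcs1 was lower at 22.6 ± 1.24 against 10.2 ± 0.118 FPKM. Of 17 interferon and MHC class I genes 2 rose and 6 fell (adjusted over the list alone 2 higher and 8 lower; camera adjusted p = 0.110, and 0.0110 without corticotrope replicate 1, range 0.0110 to 0.329). The interferon list's counts were 1 higher and 6 lower without corticotrope replicate 1, 1 higher and 5 lower without corticotrope replicate 2 or melanotrope replicate 2 and 2 higher and 2 lower without melanotrope replicate 1. B2m was lower at 34.7 ± 5.60 against 17.0 ± 1.72 and Irf7 higher at 1.41 ± 0.0327 against 3.24 ± 0.669 FPKM. Of 11 cell cycle genes 2 rose and 1 fell, against 2 higher and 0 lower (0 lower at an unadjusted p under 0.05) without corticotrope replicate 2 and 1 higher and 1 lower without melanotrope replicate 1 or 2. Mcm2 was higher at 8.34 ± 0.265 against 13.3 ± 0.467 FPKM (deposited scale adjusted p = 0.151; range 3.16e-05 to 0.151) and Cenpe lower at 1.60 ± 0.272 against 0.107 ± 0.0217 FPKM. Of 5 cyclin dependent kinase inhibitors Cdkn1a fell, at 3.64 ± 0.637 against 0.341 ± 0.0509 FPKM (adjusted over the list alone 0 higher and 1 lower; camera adjusted p = 0.306). The kinase inhibitors had 0 higher and 0 lower (0 higher and 2 lower at an unadjusted p under 0.05) without corticotrope replicate 1 and 0 higher and 0 lower (1 higher and 0 lower at an unadjusted p under 0.05) without corticotrope replicate 2. Cdkn1a and Cenpe did not pass the expression filter when either corticotrope library was left out, so they were not tested there. For the cell cycle list the counts adjusted over the list alone were 2 higher and 1 lower (camera adjusted p = 0.999). As deposited, there were 4 higher and 13 lower immediate early and dissociation genes, 0 higher and 14 lower sterol synthesis genes and 1 higher and 14 lower interferon and MHC class I genes. The cell cycle list had 1 higher and 7 lower there, and the kinase inhibitors 0 higher and 4 lower. Of 79 genes on the cytoplasmic ribosomal list 7 rose and 1 fell, against 14 and 2 at an unadjusted p under 0.05 (limma). Adjusted over the list alone 0 rose and 0 fell. The list was drawn by symbol and is not limited to protein-coding genes. The ribosomal counts were 0 higher and 2 lower (4 higher at an unadjusted p under 0.05) without corticotrope replicate 1, 2 higher and 0 lower (1 lower at an unadjusted p under 0.05) without corticotrope replicate 2, 4 higher and 0 lower (1 lower at an unadjusted p under 0.05) without melanotrope replicate 1 and 2 higher and 1 lower without melanotrope replicate 2. Markers of other anterior-lobe lineages were lower (13 of 13) and those of the posterior lobe and glia higher (6 of 8) in the same melanotrope libraries. The ribosomal list's median log2 fold change was 0.14 (camera adjusted p = 0.0133; adjusted p = 0.999 with an estimated correlation). The call was lost without corticotrope replicate 1 (adjusted p = 0.719) and without melanotrope replicate 2 (0.393; range 1.11e-04 to 0.719), and on the deposited scale the direction turned, with 0 higher and 62 lower. Of the sex-linked genes the 4 measured Y-linked members did not pass the test (on the deposited scale 0 higher and 3 lower, and 0 higher and 1 lower (0 higher at an unadjusted p under 0.05) without melanotrope replicate 1), and Xist was at 0.02 FPKM or less, as deposited, in each library (camera adjusted p = 0.821).

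An FDR under 0.05 was given to 754 transcripts of 520 genes in the authors' deposited table. On the longest transcript of each gene that was 503 genes in the authors' deposited table, 268 higher and 235 lower in melanotropes. Of these, 499 were called here in the same direction and 0 in the opposite direction. Of the 4859 genes called here, 4360 did not pass that FDR on their longest transcript. Pomc passed it (getDiffExpression FDR 1.01e-73) but was not called here (limma adjusted p = 0.222). Both sets of calls rest on the same FPKM columns, so their overlap is not independent evidence.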

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

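Alternatives for the pseudocount, transcript, prior variance, Pomc-free sums and left-out markers of other cell types were chosen after the data were seen, and the rest beforehand. The count of 4859 genes stayed within 1.5 times under median-ratio scaling (4865), no filter (5120), a mean-based filter (4602), Pomc-free sums (4796) and a single prior variance (4769). The split moved with Pomc-free sums, to 2852 higher and 1944 lower against 2469 and 2390, so the near-even split depends on the scaling. Taking the markers of other cell types out of the same calls left 4812. That involved no new fit, so it cannot show whether RNA of those cells affects other genes. On the deposited scale it was 9726, with 939 higher and 8787 lower in melanotropes, and the equal column sums with a larger Pomc share in melanotropes account for the direction, since equal sums of the other transcripts gave a median log2 fold change of 0.06. Leaving out 1 library gave 3076 to 3427 genes, with 1403 to 1760 higher, where the lone library was assumed to vary like the others. A pseudocount of 5 gave 404 genes at 2-fold against 1158 and one of 0.1 gave 784 higher and 890 lower, since a larger one shrinks the folds of low genes more. Of 10 lists called by camera, 0 passed with an estimated correlation (camera, 0 also at an unadjusted p under 0.05). That version tests on the 2.00 residual degrees of freedom, so a miss need not come from correlation between genes. For corticotrope markers the estimated correlation of -0.0272 lay below the preset 0.01, yet the unadjusted p rose from 7.39e-04 to 0.0744 (camera). Fry, which does not compare a list with other genes, called 14 lists. The unfolded protein response (fry adjusted p = 0.135), cadherin (0.0802) and ribosomal (0.473) lists, called by camera, were not among them. The gap between the lowest correlation of replicates and the highest between cell types was 0.0705 and 0.117 over genes of more than 10 FPKM. Of the results called after rescaling, Ifi27 (adjusted p = 0.199) and the ribosomal protein list (adjusted p = 0.434) turned on the deposited scale and were not called there. Ddx3y, not called on either scale, turned too. The medians of 10 of 31 lists turned from above to below 0 there, among them the unfolded protein response (-0.10), cadherins (-0.22) and granins (-0.29). Camera's direction, which is relative to other genes, turned for 12 lists, and 3 of these passed the test on the deposited scale (blood and immune 0.0422, potassium channels 0.0354 and semaphorins 0.0360). With replicate number as a block, 7202 genes were called, all 4859 among them, and Pomc (adjusted p = 7.63e-09), Tbx19 (0.00699), Meg3 (0.00211), Ddx3y (0.0397), Eif2s3y (0.00107) and the granin list (0.0294) gained a call. Same-numbered libraries share only a number, per the labels, and their deviations correlated at 0.525 across genes. The main fit holds no term for such shared deviations, and whether they come from a pairing is not known from the labels. Of the named genes' other comparisons with an alternative 1667 were the same, 37 lost and 10 gained the call, and of the lists' 442, 14 and 8. DESeq2 and the exact test were not run, because the columns hold no counts. The implied read count was lowest in corticotrope replicate 1, and values near 0.01 FPKM are at the rounding limit.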

Other observations

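Some genes outside the fixed lists, picked out after their values were seen, are given one by one and stand for no group. Slc17a6, the vesicular glutamate transporter VGLUT2, was at 15.1 ± 0.671 against 0.0893 ± 0.0292 FPKM in corticotropes against melanotropes (SD, n = 2), a log2 fold change of -3.88 (limma adjusted p = 2.06e-05). Gad2, an enzyme of GABA synthesis, went the other way at 3.33 ± 0.0111 against 20 ± 1.81 FPKM (log2 fold change 2.27), as did the glycine receptor subunit Glra2 at 1.80 ± 0.271 against 11.4 ± 1.16 and the incretin receptor Glp1r at 2.09 ± 0.441 against 12.2 ± 0.0644 FPKM. The peptide genes Nmb at 59.7 ± 8.41 against 10.8 ± 0.288 and Cartpt at 5.29 ± 1.05 against 0.396 ± 0.0268 FPKM were lower in melanotropes. The imprinted gene Mest was higher at 54.9 ± 4.33 against 223 ± 10.6 FPKM, while Meg3, also imprinted, was at 86.2 ± 27.9 against 71.2 ± 28.0 FPKM and did not pass the test (adjusted p = 0.515). Rasd1, a dexamethasone-induced Ras-like gene outside the fixed glucocorticoid list, was at 115 ± 3.75 against 6.82 ± 0.234 FPKM (log2 fold change -3.89), and the motor neuron and islet factor Mnx1 at 12.8 ± 1.69 against 0.0416 ± 0.0103 FPKM.

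The tests of the patterns below, and their bounds, were chosen after the results were seen, and those for expression by corticotropes themselves, other anterior-lobe cells and the glucocorticoid list were rewritten after their first outcome. Melanotrope markers stood at a similar fraction of their melanotrope level in the corticotrope libraries, from 13.2% for Oacyl to 21.3% for Esm1, a range of 1.62 times over the 7 markers fixed beforehand, against 37.6 times for 5 corticotrope markers in melanotropes, leaving out Gpr165, which rose, and 6.5 times also without Pcsk1. Exchange of reads between libraries at sequencing would leave a floor in both directions, and 41 genes higher in corticotropes lay below 10% in melanotropes (37 to 47 with 1 library left out), which argues against it. A candidate explanation is melanotropes carried into the anterior-lobe sort, since both cell types carry GFP and only dissection parts them, and the range of 1.62 times lies between the bounds set for one shared ratio (1.5) and for separate ratios (3), as do 1.90 without corticotrope replicate 1, 1.54 without melanotrope replicate 1 and 1.70 without melanotrope replicate 2, while 1.47 without corticotrope replicate 2 lies under the lower bound. Carryover would hold every gene that melanotropes make at or above its share, and Scn7a (1.94%), Col13a1 (4.34%) and Bcan (7.11%) lay below the 7 markers, so that it could give the markers at most 1.94% if melanotropes make Scn7a, which is also on the fixed list of posterior lobe and glia markers. Carryover and low expression of these genes by corticotropes cannot be told apart here, because no library of known purity was compared and the cells that make those 3 genes, which were singled out for their low ratios, are not known from these data.

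Transcripts of other pituitary hormones were abundant in the corticotrope libraries, where Gh stood at 13.5% and 12.3% of the longest Pomc transcript, as deposited. Other anterior-lobe cells, or their RNA, may have entered the sort despite the GFP gate. Their receptors and transcription factors would then be higher in corticotropes as well, and 7 of 7 non-hormone genes of the list fixed beforehand were (Pou1f1, Ghrhr, Gnrhr, Nr5a1, Gata2, Foxl2 and Dlk1), but they are part of the 13 of 13 already seen and so do not count for it. Low expression by corticotropes themselves stays open too, because the Gh to Pomc ratios of the corticotrope libraries were 1.09 times apart, which either explanation allows, so both cannot be told apart here.

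The glucocorticoid response list fell along with Nr3c1, with a median log2 fold change of -1.24 against -0.13 to 0.20 for 95% of 10000 random lists matched on expression, which describes the pattern and tests no explanation. A hypothesis is that the lower receptor level in melanotropes lowers its targets, and another is that RNA of other anterior-lobe cells in the corticotrope libraries, whose markers were also lower in melanotropes (13 of 13), may give part of it. Telling them apart would need the receptor or those markers to vary within a cell type. Replicates differed by at most 1.04 times in Nr3c1, and the corticotrope libraries by 1.29 times in the median of those markers, so both explanations cannot be told apart here. The 4 members that rose, Per1 (called under 11 of 15 alternatives), Errfi1, Dusp1 and Gadd45b, go against a uniform effect.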
